A study of Mus musculus with 12 samples.

How the data were processed

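RNA was measured by sequencing in 12 kidney cortex libraries from male C57BL6/J mice, 8 weeks old per the labels, in 4 groups of 3 libraries. The mice had received a liquid Lieber-DeCarli diet with ethanol, or an isocaloric pair-fed diet with maltose-dextrin in place of ethanol, for 6 weeks. The ethanol content was raised in steps and ended at 6%. Within each diet, 1 group was injected intraperitoneally with 10 mg/kg lipopolysaccharide (LPS), the outer membrane component of Gram-negative bacteria that TLR4 recognises, and 1 group with saline, 4 hours before the tissue was taken. The labels give the source as whole kidney and the tissue region as cortex, and the extraction protocol describes cortex sections. Per the labels' protocols, total RNA was isolated with the mirVana kit and libraries were made with a stranded total RNA kit that removes ribosomal RNA (TruSeq Stranded Total RNA with Ribo-Zero Gold). The labels number 3 replicates per group and do not say in words that each came from a different mouse, so the p-values measure the spread between these libraries. The groups are called PF, PF_LPS, EtOH and EtOH_LPS.

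The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, relative to the mapped fragments of the library) for 47719 Ensembl genes in all 12 libraries. Per the submitters' processing notes, the tools were FastQC 0.10.1, TopHat2 2.0.4, Cufflinks 2.2.1, Cuffdiff 2.1.1 and Cuffnorm, with genome build mm10. The strand setting of the alignment and the annotation release are not given in the sources used here, so values of a gene and of an overlapping antisense gene may share fragments. FPKM are not counts, and no count model was run. Gene symbols, biotypes, transcript GC content and coordinates were taken from GENCODE M21 (GRCm38, the assembly also called mm10). Of the genes in the table, 47305 matched it by Ensembl identifier and 414 did not.

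The deposited FPKM summed to between 1005219 and 1935824 per library, so the sum was not fixed by the authors' scaling. Fragment totals are not in the table. The low values of a gene lie on steps of 1 fragment's worth, and the modal step of 17.1 to 22.1% of the low genes gave the depth of each library relative to the first PF library. That estimate was between 0.987 and 1.199 for the other PF libraries, 0.929, 0.72 and 0.942 for EtOH, 0.744, 0.491 and 0.688 for PF_LPS, and 0.667, 0.697 and 0.762 for EtOH_LPS. It does not give whole fragments for all genes, so it was used as a description only. Genes at 1 FPKM or more numbered 12354 to 13092 per library. All 37 mitochondrial genes of the table are listed at 0 in every library, so a 0 can stand for a feature that was masked or not estimated.

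Values were analysed as log2(FPKM + 1), so every fold change given is on that scale and understates the change of genes at low FPKM. Genes at 1 FPKM or more in at least 3 of the 12 libraries were tested, 14109 genes, of which 11674 were protein coding and 654 were small RNA genes. In limma 3.58.1 (R 4.3.3), 1 mean per group was fitted to all 12 libraries, with moderated variances that follow the intensity trend and a robust prior. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. Every adjusted p of a gene in the text comes from this limma fit. Errors beside fold changes are standard errors of the fit, and errors beside FPKM are standard deviations over 3 libraries. The 6 contrasts were LPS against saline in each diet, ethanol against pair-feeding without LPS, with LPS and averaged over both, and the interaction of diet and LPS. The series design names the first 5, and the interaction was added here. A permutation test of 3 against 3 libraries could not reach p under 0.1, so none is given for single genes.

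For gene groups, 54 lists with 1193 members were fixed from textbook knowledge. Of the members 1190 matched the annotation, 5 of them by an older symbol, and 992 passed the expression filter. The 50 lists with at least 5 tested members were tested with camera in limma, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. The p-values were adjusted over the lists of 1 comparison. Camera asks whether a list moved relative to the other genes. The lists of adipose tissue (3 tested genes), adrenal (2), skeletal muscle (1) and mitochondrially encoded genes (0) were too short for it. Counts of list members past the threshold are given over all genes tested and, where stated, adjusted over the list alone.

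Genes were named by rule. For each comparison, the rule took the 8 highest and 8 lowest fold changes among genes past the threshold whose groups did not overlap (within both LPS states for the pooled contrast) and whose higher group mean was at least 5 FPKM, leaving out predicted and small RNA genes. It added a panel of 12 genes and up to 4 members of a list that camera called or that had at least 3 members past the threshold. Where fewer than 8 genes passed, the 5 genes with the smallest p were added. Some genes that the rule took are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

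The grouping, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. These alternatives were a pseudocount of 0.1, no expression filter, a filter of 5 FPKM (9219 genes), equal total FPKM, quantile normalization, median-ratio size factors, a constant prior variance, library quality weights, the replicate number as a block, only the groups compared, no LPS term in the pooled contrast, an estimated correlation for camera, and leaving out each library in turn. Chosen after seeing the data were the removal of small RNA genes, a correction of each library for its trend with GC content (lowess, span 0.3), leaving out the 2 LPS libraries with the strongest such trend, and list tests of the interaction without PF_LPS library 2. Whether replicate numbers pair the libraries was checked with correlations of deviations from group means, and they were not treated as pairs. Each contrast was recomputed after regrouping the libraries, over all 10 splits of 3 against 3 or, for the pooled contrast and the interaction, over 100 splits drawn within the LPS groups. Intervals of list medians came from 2000 bootstrap draws over list members, so they leave out the spread between libraries.

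The fits were tested on simulated data of 14109 genes, with the PF means in every group, the observed spread and independent normal noise. In each contrast 100 genes per fold size were changed, all with a PF mean of at least 5 FPKM on the log2 scale. The recovered shares therefore do not cover genes at lower levels, and these data held no GC trend or correlation between genes. Each gene had 1 spread in all groups. The shares also depend on how many genes change, because p-values are adjusted over all genes. The simulated contrasts called 87 to 173 genes. The real ones called 2561 and 2406 for LPS in pair-fed and ethanol-fed mice, and 4 and 14 for ethanol without and with LPS. The shares therefore do not carry over directly to the real contrasts. At a log2 change of 1, the limma fit recovered 48% for LPS in pair-fed mice, 53% for LPS in ethanol-fed mice, 47% for ethanol without LPS, 35% for ethanol with LPS, 68% for the pooled contrast and 16% for the interaction. At a log2 change of 2, the shares were 93, 88, 85, 89, 96 and 65%. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.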

Results

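RNA of kidney cortex was profiled in 12 libraries from male C57BL6/J mice, 3 each for pair-feeding (PF), pair-feeding with LPS (PF_LPS), ethanol diet (EtOH) and ethanol diet with LPS (EtOH_LPS). LPS was given at 10 mg/kg, 4 hours before the tissue was taken. Depth, estimated from the steps between low values relative to the first PF library, ranged from 0.491 in PF_LPS library 2 to 1.199 in PF library 3. It was at most 0.762 in the 6 LPS libraries. Genes above 0 FPKM numbered 23188 to 27808 per library. Small RNA genes held 31.7 to 44.86% of the summed FPKM, led by Rny3 with 6.62% and Rn7sk with 5.16% on average, and Kap, a kidney androgen-regulated gene of the proximal tubule, held 4.61%. Unprocessed pseudogenes that are nuclear copies of mitochondrial sequence also ranked among the top genes, with 4.81% for Gm29216 and 4.68% for Gm28437. Each library correlated with the others of its group at a mean r of 0.9189 to 0.9618 over the genes tested. The first principal component, 43.4% of the variance, separated the 6 LPS libraries from the 6 saline libraries. Relative to the mean of their own group, genes of high GC content were low in PF_LPS library 2, EtOH_LPS library 1 and PF library 1. The slopes of these deviations were -0.412, -0.308 and -0.248 log2 units per 10% GC, against -0.077 to 0.214 in the other 9 libraries. Taken within groups, the slopes balance inside each group and cannot show a difference in GC trend between groups.

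LPS in pair-fed mice raised cytokine, chemokine and interferon-response genes and lowered single genes such as Tek and Cyp24a1. Cxcl10, a chemokine that attracts activated T cells (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, mm10), rose from 2.38 ± 1.07 to 1766 ± 246 FPKM (SD, n = 3 per group), a log2 fold change of 9.07 ± 0.26 (SE; limma adjusted p = 5.33e-10). Lcn2, which encodes the siderophore-binding protein NGAL (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 0.442 ± 0.267 to 179 ± 79.4 FPKM (log2 fold change 6.85 ± 0.46; adjusted p = 8.66e-07). Tek, the angiopoietin receptor of endothelial cells (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976), fell from 10.9 ± 1.4 to 1.03 ± 0.09 FPKM (log2 fold change -2.55 ± 0.16; adjusted p = 3.09e-07). Cyp24a1, the enzyme that inactivates vitamin D hormones (ENSMUSG00000038567, chromosome 2, 170482708 to 170497145), fell from 47.7 ± 6.5 to 1.46 ± 0.65 FPKM (log2 fold change -4.33 ± 0.64; adjusted p = 0.000866). Of 14109 genes, 1589 rose and 972 fell by limma, 1010 and 330 of them by at least 1 log2 unit.

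Interferon and cytokine genes were among those with the highest fold changes in pair-fed mice. All 34 tested genes of the type I interferon list rose, and all 34 did when adjusted over the list alone, with a median log2 fold change of 4.34 (camera adjusted p = 8.86e-48; adjusted p = 0.00235 with an estimated correlation). Ifit1, Ifit2 and Ifit3, interferon-induced antiviral proteins, rose by 8.45, 7.99 and 7.31 log2 units. In the interferon-gamma and antigen presentation list, 26 of 29 genes rose and 3 did not pass, 27 adjusted over the list alone (camera adjusted p = 2.51e-29; adjusted p = 0.0307 with an estimated correlation). The guanylate-binding proteins Gbp2 and Gbp5 rose by 6.70 and 6.30. Of 30 inflammatory cytokines and chemokines 29 rose, also adjusted over the list alone (adjusted p = 5.59e-31; adjusted p = 0.00235 with an estimated correlation). The chemokines Cxcl1 and Ccl2 rose by 7.27 and 6.56, and Il6 by 5.91. Tnf reached 1.34 ± 0.43 FPKM from 0.131 ± 0.065 (log2 fold change 1.03 ± 0.17; limma adjusted p = 0.00116). The list of NF-kB pathway and feedback genes rose in 22 of 23 members, 23 adjusted over the list alone (adjusted p = 1.75e-21; adjusted p = 0.00235 with an estimated correlation). Tnfaip3, an inhibitor of NF-kB signalling, rose by 4.28 and Birc3 by 3.77. Of 18 genes of TLR4 signalling 6 rose and 12 did not pass, 8 adjusted over the list alone. The LPS co-receptor Cd14 rose by 4.36 and Tlr2 by 5.10. The median of the TLR4 list was 0.40 as deposited and turned to -0.043 with equal total FPKM (camera adjusted p = 0.00306; adjusted p = 0.13 with an estimated correlation).

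Acute-phase genes rose in the same mice, as did some of the injury and stress genes. All 18 acute-phase genes rose, also adjusted over the list alone (camera adjusted p = 2.24e-19; adjusted p = 0.0535 with an estimated correlation). Fgg, the fibrinogen gamma chain, rose from 5.55 ± 0.83 to 1245 ± 89 FPKM. Saa1, serum amyloid A1, was listed at 0 in the 3 PF libraries and at 312, 131 and 386 FPKM in the 3 PF_LPS libraries. Of 20 tubular injury markers 10 rose and 10 did not pass, 14 adjusted over the list alone (adjusted p = 6.14e-10; adjusted p = 0.115 with an estimated correlation). Havcr1, the kidney injury molecule KIM-1, rose from 1.28 ± 0.56 to 41.7 ± 17.8 FPKM (log2 fold change 4.18 ± 0.60; limma adjusted p = 0.00062). Immediate early genes rose in 15 of 21 cases, 18 adjusted over the list alone, with Atf3 at 3.95 (adjusted p = 2.6e-10; adjusted p = 0.0637 with an estimated correlation). Of 22 genes of cell death pathways 14 rose and 1 fell, 15 and 1 adjusted over the list alone (adjusted p = 4.99e-09; adjusted p = 0.0307 with an estimated correlation). The inflammatory caspase Casp4 rose by 4.10 and the necroptosis effector Mlkl by 3.69. Of 29 genes of the unfolded protein and integrated stress response 15 rose and 14 did not pass, 16 adjusted over the list alone (adjusted p = 3.61e-06; adjusted p = 0.0925 with an estimated correlation). Heat-shock genes rose in 7 of 18 cases, 10 adjusted over the list alone, including the inducible Hsp70 gene Hspa1b at 1.81 (adjusted p = 0.000245; adjusted p = 0.0972 with an estimated correlation). Glucocorticoid-responsive genes rose in 12 and fell in 1 of 18 cases, 14 and 1 adjusted over the list alone, with the metallothioneins Mt2 at 5.33 and Mt1 at 3.67 (adjusted p = 2.23e-08; adjusted p = 0.0399 with an estimated correlation).

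Endothelial and immune cell markers moved in different directions after LPS in pair-fed mice. Of 16 endothelial cell markers 2 rose and 11 fell, also adjusted over the list alone, with a median log2 fold change of -1.17 (camera adjusted p = 1.85e-06; adjusted p = 0.202 with an estimated correlation). Tek, Ptprb, the VEGF receptor Kdr and Emcn fell by 2.55, 2.19, 2.01 and 1.97 log2 units. Of 11 genes of endothelial adhesion and activation 8 rose and 1 fell, 9 and 1 adjusted over the list alone (adjusted p = 1.2e-06; adjusted p = 0.00806 with an estimated correlation). The leukocyte adhesion molecules Vcam1 and Icam1 rose by 4.29 and 4.14. Neutrophil and inflammatory monocyte markers rose in 13 and fell in 1 of 16 cases, 14 and 1 adjusted over the list alone, with S100a8 at 5.42 and S100a9 at 5.22 (adjusted p = 6.38e-10; adjusted p = 0.0604 with an estimated correlation). Macrophage and dendritic cell markers rose in 5 and fell in 1 of 16 cases, the same numbers adjusted over the list alone, with a camera adjusted p of 0.663.

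Among tubular genes of pair-fed mice, 6 of 38 proximal tubule transporters fell, 2 rose and 30 did not pass, with the same numbers adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.443 with an estimated correlation). The sulfate transporter Slc13a1 rose from 223 ± 8 to 987 ± 198 FPKM (log2 fold change 2.12 ± 0.21; limma adjusted p = 2.06e-05), and the anion exchanger Slc26a1 fell by 1.14 log2 units. Slc34a1, the main phosphate transporter of the proximal tubule, was at 706 ± 159 and 538 ± 115 FPKM (log2 fold change -0.39 ± 0.24; limma adjusted p = 0.291). Of 12 intercalated cell markers 5 fell, and 1 rose and 5 fell adjusted over the list alone (adjusted p = 0.00356; adjusted p = 0.202 with an estimated correlation). The proton pump subunit Atp6v1c2 fell by 1.59 and the anion exchanger Slc4a1 by 1.57. Of 10 principal cell markers of the collecting duct 3 fell, also adjusted over the list alone, including the vasopressin receptor Avpr2 at -1.27 (adjusted p = 0.0434; adjusted p = 0.491 with an estimated correlation). Sucnr1, the succinate receptor, fell from 52.2 ± 13.2 to 6.64 ± 1.26 FPKM (log2 fold change -2.79 ± 0.31; limma adjusted p = 5.68e-05). Across genes, the fold change and GC content had a Spearman correlation of -0.309. Scaling to equal total FPKM moved the median of all genes by -0.403 log2 units and the calls to 844 higher and 2679 lower, 24% higher instead of 62%. The count of lower genes was 472 without PF library 2 and 502 without PF library 3.

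**Figure D1:**
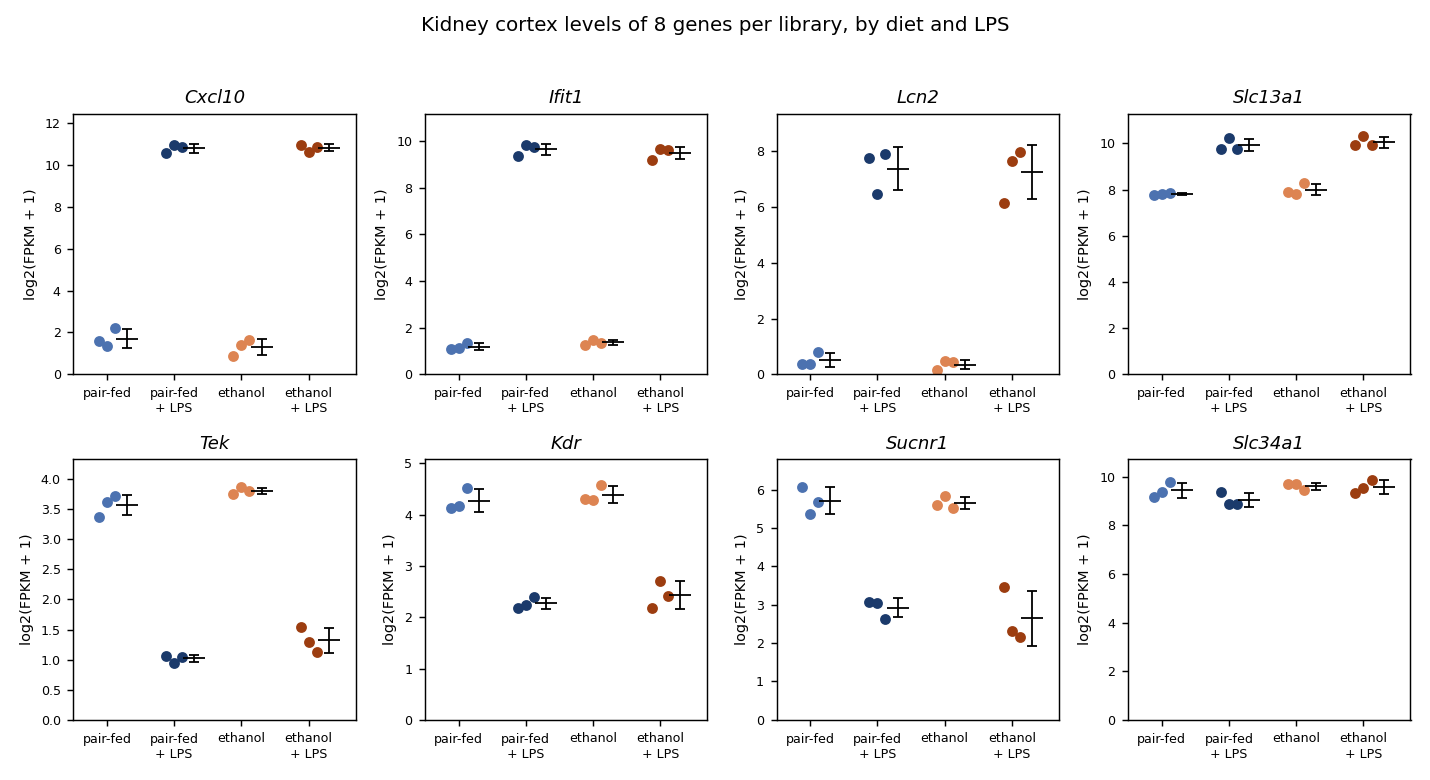
FPKM of 8 genes on a log2(FPKM + 1) axis in the 12 libraries of the 4 groups, with points for libraries and black bars for the mean and SD of 3 libraries. Cxcl10, Ifit1 and Lcn2 were higher in LPS libraries of both diets, Tek, Kdr and Sucnr1 were lower, Slc13a1 rose in pair-fed mice from 223 to 987 FPKM, and Slc34a1 did not pass the threshold in either diet.

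LPS in ethanol-fed mice also raised inflammatory and antiviral transcripts. Cxcl10 rose from 1.52 ± 0.64 to 1802 ± 214 FPKM (log2 fold change 9.51 ± 0.26; limma adjusted p = 3.84e-10), and Ifit1 from 1.59 ± 0.21 to 719 ± 123.2 FPKM (log2 fold change 8.11 ± 0.18; adjusted p = 2.01e-10). Spp1, the secreted phosphoprotein osteopontin, rose from 378 ± 62 to 3932 ± 916 FPKM (log2 fold change 3.36 ± 0.23; adjusted p = 8.81e-07). Tek fell from 13 ± 0.52 to 1.51 ± 0.37 FPKM, Sucnr1 from 49.5 ± 5.8 to 5.84 ± 3.68, and Cyp26b1, a retinoic acid hydroxylase, from 7.12 ± 1.78 to 0.0775 ± 0.0262. By limma 1504 of 14109 genes rose and 902 fell, 993 and 291 of them by at least 1 log2 unit.

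The lists that rose in pair-fed mice were tested in ethanol-fed mice as well, and their shifts were not all of like size. All 34 type I interferon genes rose, also adjusted over the list alone, with a median of 4.05 (camera adjusted p = 6.58e-48; adjusted p = 0.0015 with an estimated correlation). Of 30 cytokines and chemokines 28 rose, 29 adjusted over the list alone (adjusted p = 1.44e-33; adjusted p = 0.0015 with an estimated correlation). Cxcl1, Ccl2 and Il6 rose by 7.67, 7.27 and 6.58. Of 23 NF-kB genes 22 rose, also adjusted over the list alone (adjusted p = 2.41e-24; adjusted p = 0.0015 with an estimated correlation). All 18 acute-phase genes rose, also adjusted over the list alone (adjusted p = 4.23e-19; adjusted p = 0.0494 with an estimated correlation). Saa1 reached 345 ± 192 FPKM. Immediate early genes rose in 18 of 21 cases, 20 adjusted over the list alone (adjusted p = 3.03e-15; adjusted p = 0.0315 with an estimated correlation). Atf3 and Btg2 rose by 4.70 and 4.12. Endothelial adhesion genes rose in 8 and fell in 1 of 11 cases, 9 and 1 adjusted over the list alone (adjusted p = 4.42e-08; adjusted p = 0.00396 with an estimated correlation). Icam1 rose by 5.27. Tubular injury markers rose in 12 of 20 cases, 15 adjusted over the list alone (adjusted p = 1.08e-10; adjusted p = 0.105 with an estimated correlation). Havcr1 rose by 3.31 and Lcn2 by 6.89. Endothelial cell markers fell in 9 and rose in 2 of 16 cases, 11 and 2 adjusted over the list alone (adjusted p = 9.36e-05; adjusted p = 0.308 with an estimated correlation). Neutrophil markers rose in 10 and fell in 1 of 16, 14 and 1 adjusted over the list alone (adjusted p = 3.98e-08; adjusted p = 0.0845 with an estimated correlation). Heat-shock genes had a median of 0.357, against 0.772 in pair-fed mice, and unfolded protein and stress genes 0.370 against 0.891. With equal total FPKM these 2 medians were 0.035 and 0.033 in ethanol-fed mice, and 0.303 and 0.391 in pair-fed mice. Other medians were closer, with 3.210 against 3.585 for interferon-gamma, 1.405 against 1.212 for cell death, 1.673 against 1.809 for glucocorticoid-responsive and 0.337 against 0.403 for TLR4 genes.

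Oxidative stress and metabolic lists were called in ethanol-fed mice after LPS. Of 32 NRF2 and oxidative stress genes 9 rose and 23 did not pass, also adjusted over the list alone, and the list median of 0.35 turned to -0.017 with quantile normalization (camera adjusted p = 0.00031; adjusted p = 0.419 with an estimated correlation). The heme-degrading enzyme Hmox1 rose from 6.27 ± 0.25 to 177 ± 107 FPKM (log2 fold change 4.45 ± 0.36; limma adjusted p = 3.78e-06), and Gclc, of glutathione synthesis, rose by 1.74. Of 30 fatty acid oxidation genes 2 rose and 28 did not pass, 0 adjusted over the list alone, and the median of 0.37 turned to -0.049 with quantile normalization (camera adjusted p = 0.0102; adjusted p = 0.497 with an estimated correlation). Angptl4, a PPAR target that inhibits lipoprotein lipase, rose from 5.55 ± 0.65 to 85.8 ± 55.6 FPKM (log2 fold change 3.41 ± 0.58; limma adjusted p = 0.00214). In pair-fed mice its log2 fold change was 1.078 ± 0.58 (adjusted p = 0.236), and the difference between diets was 2.33 ± 0.82 (interaction adjusted p = 0.987). Cyp24a1, which had fallen in pair-fed mice, had a log2 fold change of -0.87 ± 0.64 here (adjusted p = 0.428), with a difference of 3.46 ± 0.90 between diets (interaction adjusted p = 0.847). Proximal tubule transporters rose in 2 of 38 cases, with a median of 0.030 as deposited that turned to -0.298 with equal total FPKM, -0.339 with quantile normalization and -0.033 with median-ratio factors (camera adjusted p = 0.774). Scaling to equal total FPKM moved the median of all genes by -0.285 and the calls to 969 higher and 1861 lower, 34.2% higher instead of 62.5%, and quantile normalization moved the median by -0.143 here and by -0.108 in pair-fed mice. The count of lower genes was 543, 566 and 582 without EtOH library 1, 2 and 3, and 522 and 525 without EtOH_LPS library 2 and 3.

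**Figure D2:**
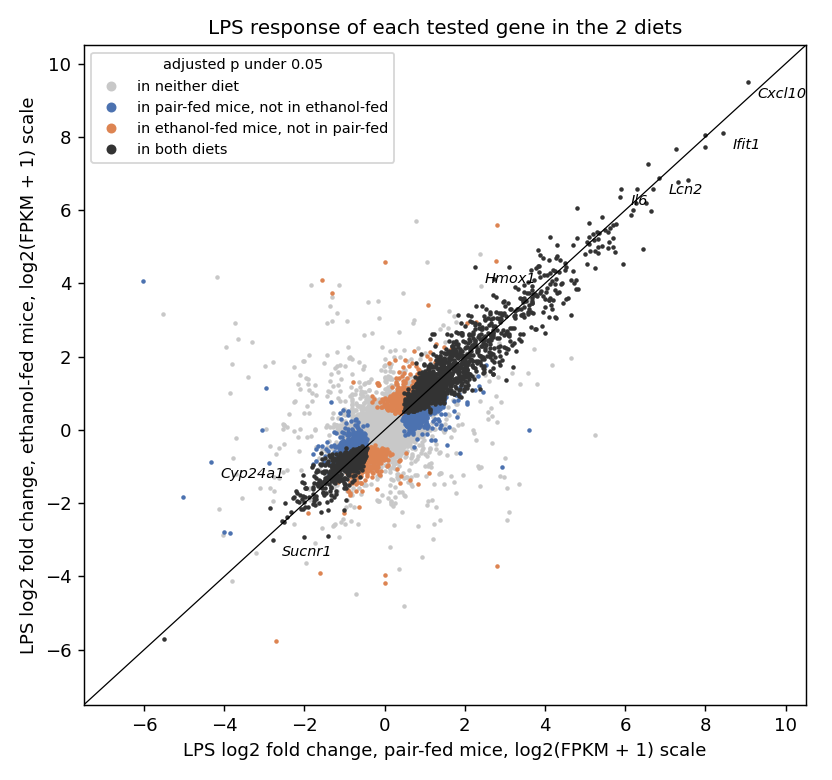
Log2 fold change after LPS in pair-fed mice (x axis, log2 units) against ethanol-fed mice (y axis, log2 units) for 14109 genes, with points for genes and the diagonal as a line of equal change. The points had a Pearson r of 0.769 across genes, and 1194 genes rose and 542 fell in both diets.

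The LPS responses of both diets, which share no library, had a Pearson r of 0.769 and a Spearman correlation of 0.68 across 14109 genes, which are not independent replicates. In both diets the LPS libraries had a low estimated depth, at most 0.762, against 0.72 to 1.199 in the saline libraries. The fold changes also correlated with GC content, at -0.309 in pair-fed and -0.103 in ethanol-fed mice. Technical differences common to the LPS libraries can therefore add to r, and their part was not measured. Of the genes called, 1194 rose in both diets, with 169 expected from independent lists, and 542 fell in both, with 62 expected. The expected numbers are a rough baseline, since both contrasts use 1 spread per gene, estimated from all 12 libraries. No gene was called in opposite directions by limma (0 genes), and 3145 of the 3231 genes called in either diet (97.3%) had fold changes of the same sign. Leaving out 1 library at a time gave r between 0.716 and 0.778. By camera with the preset correlation 17 lists rose and 4 fell in pair-fed mice and 19 rose and 1 fell in ethanol-fed mice, of which 7 and 9 rose and 0 fell with an estimated correlation.

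Ethanol without LPS (EtOH against PF) moved few single genes past the threshold. Slc6a15, a transporter of neutral amino acids (ENSMUSG00000019894, chromosome 10, 103367783 to 103419377), fell from 14.7 ± 1.2 to 4.76 ± 0.41 FPKM (log2 fold change -1.45 ± 0.20; limma adjusted p = 0.0478). The other 3 genes called by limma were small RNA genes of 108 to 126 exonic bases, each listed at 0 in 9 of the 12 libraries. Mir1966 (chromosome 8, 105615466 to 105615573) was at 13.3, 17.4 and 13.3 FPKM in the EtOH libraries. Gm24337 (chromosome 4, 5687677 to 5687802) was at 22.5, 29.3 and 7.45 FPKM in the same libraries, and Gm22586 (chromosome 8, 64161405 to 64161526) at 7.83, 7.93 and 6.53 FPKM in the PF libraries. Of 14109 genes 2 rose and 2 fell, and 521 had an unadjusted p under 0.05. Cyp2e1, the ethanol-metabolising cytochrome, was at 1097 ± 146 FPKM in PF and 664 ± 134 in EtOH (log2 fold change -0.73 ± 0.22; limma adjusted p = 0.95). Lcn2, Havcr1, Il6 and Ccl2 had log2 fold changes of -0.16, -0.58, 0.073 and -0.11, each with an adjusted p of 1.

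Small shifts of whole lists were found by camera in this comparison, 8 up and 6 down of 50, and 0 with an estimated correlation, where the lowest adjusted p was 0.175. For cell proliferation, 0 of 20 genes passed over all genes and 5 fell adjusted over the list alone, with a median of -0.33 (camera adjusted p = 1.69e-06; adjusted p = 0.32 with an estimated correlation). The 17 male-biased kidney genes had a median of -0.57, with 0 past the threshold and 1 higher and 6 lower adjusted over the list alone (adjusted p = 5.69e-06; adjusted p = 0.304 with an estimated correlation). Fatty acid oxidation genes had a median of -0.26, with 0 of 30 past the threshold and 0 adjusted over the list alone (adjusted p = 6.43e-06; adjusted p = 0.42 with an estimated correlation), and the median was -0.163 with equal total FPKM and -0.157 with quantile normalization. Principal cell markers of the collecting duct had a median of 0.39, with 0 of 10 past the threshold and 2 higher adjusted over the list alone (adjusted p = 2.57e-06; adjusted p = 0.182 with an estimated correlation). Medulla-enriched markers had a median of 0.37 (adjusted p = 0.0123; adjusted p = 0.182 with an estimated correlation). Liver markers had a median of 0.29 (adjusted p = 0.0297; adjusted p = 0.443 with an estimated correlation). Small RNA genes held 40.1 to 44.22% of the summed FPKM in PF and 34.62 to 34.87% in EtOH. With median-ratio factors 2 genes were higher and 1 lower, 66.7% higher instead of 50%. The count of lower genes was 5 without EtOH library 1. It was 1 without PF library 3, EtOH library 2, EtOH library 3, EtOH_LPS library 1 or EtOH_LPS library 2. Slc6a15 stayed past the threshold in 7 of 21 alternatives, with adjusted p from 0.000134 to 0.255. It was also lost with small RNA genes left out, an alternative outside these 21 in which limma called 0 genes.

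Ethanol with LPS (EtOH_LPS against PF_LPS) gave more calls near the threshold than ethanol without LPS, 14 against 4. That order turned under some alternatives, such as equal total FPKM (2 against 4), the replicate block (2 against 3) and no filter (1 against 8). The neutrophil chemoattractant Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938) was at 30.2 ± 7.7 FPKM in PF_LPS and rose to 78.1 ± 17.6 in EtOH_LPS (log2 fold change 1.35 ± 0.21; limma adjusted p = 0.0488). The small GTPase Rnd3 rose from 24.4 ± 1.8 to 62.6 ± 21.1 (1.28 ± 0.20; adjusted p = 0.0495). Cyp2a5, a cytochrome P450 of xenobiotic metabolism (ENSMUSG00000005547, chromosome 7, 26835305 to 26843548), fell from 129 ± 12 to 41.5 ± 8.1 FPKM (-1.63 ± 0.23; adjusted p = 0.0442). Hsd11b1, which regenerates active glucocorticoid, fell from 137 ± 52 to 36.7 ± 11.1 FPKM (-1.83 ± 0.29; adjusted p = 0.0495). Parp11, a mono-ADP-ribosyltransferase (ENSMUSG00000037997, chromosome 6, 127446840 to 127494261), fell from 19.3 ± 1.3 to 7.75 ± 1.98 FPKM (-1.24 ± 0.17; adjusted p = 0.0442). By limma 5 of 14109 genes rose and 9 fell, and 1524 had an unadjusted p under 0.05. Slc6a15 and Trim14 fell by 1.29 and 1.09 log2 units, and Limch1 rose by 0.98. The small RNA gene Gm23731 (chromosome 2, 102897960 to 102898066) was at 19.1, 18.6 and 33.5 FPKM in EtOH_LPS and listed at 0 in the other 9 libraries. The difference between the ethanol effects with and without LPS was 1.25 for Cxcl2 (interaction adjusted p = 0.847), 1.29 for Rnd3 (0.841), -0.96 for Hsd11b1 (0.987) and -0.85 for Parp11 (0.86).

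Inflammatory transcripts of the panel did not pass the threshold between diets after LPS. Il6 was at 63 ± 15.4 FPKM in PF_LPS and 106 ± 17 in EtOH_LPS (log2 fold change 0.75 ± 0.19; limma adjusted p = 0.168), and Nos2 at 8.04 ± 2.78 and 3.08 ± 1.25 (-1.15 ± 0.27; adjusted p = 0.133). Lcn2 was at 179 ± 79 and 172 ± 93 (-0.12 ± 0.46; adjusted p = 0.949). Hmox1, chosen after its values were seen (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), was at 39 ± 14.7 and 177 ± 107 FPKM in these groups (2.06 ± 0.36; adjusted p = 0.0754, from 0.0431 to 0.212 over 21 alternatives). Its adjusted p was 0.0451 without PF_LPS library 1 and 0.0431 without EtOH_LPS library 1. Camera found 20 lists up and 6 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.0699. The 34 type I interferon genes had a median of -0.33, with 0 past the threshold and 9 lower adjusted over the list alone (camera adjusted p = 1.9e-08; adjusted p = 0.137 with an estimated correlation). The 38 proximal tubule transporters had a median of 0.38, with 0 past the threshold and 10 higher adjusted over the list alone (adjusted p = 1.9e-08; adjusted p = 0.115 with an estimated correlation). Immediate early genes had a median of 0.40, with 0 of 21 past the threshold and 7 higher adjusted over the list alone (adjusted p = 6.11e-08; adjusted p = 0.137 with an estimated correlation). Cell proliferation genes had a median of -0.51, with 0 of 20 past the threshold and 1 higher and 10 lower adjusted over the list alone (adjusted p = 7.35e-07; adjusted p = 0.171 with an estimated correlation). Neutrophil markers had a median of -0.34, with 1 of 16 past the threshold, lower, and 2 lower adjusted over the list alone (adjusted p = 0.000871; adjusted p = 0.251 with an estimated correlation). With equal total FPKM the medians were -0.070 for type I interferon genes, -0.168 for neutrophil markers, 0.644 for proximal tubule transporters and 0.665 for immediate early genes.

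The fold change of ethanol with LPS had a Spearman correlation of 0.347 with GC content across genes, and 1 library of each group, PF_LPS library 2 and EtOH_LPS library 1, stood apart in GC trend. With the GC trend removed 14 genes were higher and 16 lower, of which 12 were among the 14 first called, and 46.7% were higher instead of 35.7%. Equal total FPKM, which moved the median of all genes by 0.195 here, gave 1 higher and 1 lower gene (50% higher), and quantile normalization 6 and 7 (46.2%). Without PF_LPS library 1 the counts of higher and lower genes were 16 and 27, without library 2 they were 2 and 5 and without library 3 they were 2 and 0. Without EtOH_LPS library 1 they were 14 and 10, without library 2 they were 1 and 0 and without library 3 they were 2 and 9. Leaving out PF library 1, 2 or 3 gave 1 and 3, 1 and 2 or 2 and 1, and leaving out EtOH library 1, 2 or 3 gave 3 and 3, 1 and 2 or 1 and 1. Cyp2a5 stayed past the threshold in 9 of 21 alternatives, Parp11 in 8, Limch1 in 6, Cxcl2 and Hsd11b1 in 5, Rnd3 and Slc6a15 in 4 and Trim14 in 2.

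Ethanol averaged over both LPS states (EtOH and EtOH_LPS against PF and PF_LPS, 6 libraries each) gave the most calls for diet. Slc6a15 fell by 1.37 ± 0.14 log2 units (limma adjusted p = 0.00263) and Cyp2a5 by 1.497 ± 0.16 (adjusted p = 0.00302), and both stayed past the threshold in 21 of 21 alternatives. Synpr, a synaptic vesicle membrane protein (ENSMUSG00000056296, chromosome 14, 13284780 to 13616340), fell from 3.87 ± 0.41 to 0.0331 ± 0.0367 FPKM without LPS and from 9.8 ± 7.45 to 0.0939 ± 0.0484 with LPS (-2.58 ± 0.37; adjusted p = 0.0263). Lpl, lipoprotein lipase (ENSMUSG00000015568, chromosome 8, 68880491 to 68907448), fell from 283 ± 49 to 80.8 ± 8.5 FPKM without LPS and from 273 ± 137 to 101 ± 47 with LPS (-1.60 ± 0.25; adjusted p = 0.0299). Gc, the vitamin D binding protein, rose from 12.1 ± 0.4 to 29 ± 7.6 FPKM and from 16.5 ± 2.4 to 59.9 ± 33.7 (1.42 ± 0.22; adjusted p = 0.0263). By limma 14 of 14109 genes rose and 31 fell, and 1334 had an unadjusted p under 0.05. Pzp, an alpha-macroglobulin, fell by 1.93, and Osgin1, an oxidative stress-induced growth inhibitor, rose by 1.55. Slc16a6, Epb41l3, Ces1d and Limch1 rose by 1.02, 0.86, 0.81 and 0.66. Ctxn3 and Hsd11b1 fell by 2.19 and 1.35. The call count includes 4 small RNA genes, each listed at 0 in 9 libraries.

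In the pooled comparison, 2 of 17 male-biased kidney genes fell and 15 did not pass, 2 higher and 11 lower adjusted over the list alone, with a median of -0.57 (camera adjusted p = 8.58e-06; adjusted p = 0.13 with an estimated correlation). The members that fell were the androgen-responsive fatty acid hydroxylases Cyp4a12a at -2.25 ± 0.36 (limma adjusted p = 0.0306) and Cyp4a12b at -0.64 ± 0.10 (adjusted p = 0.0306), near-identical paralogs whose shared fragments make their separate values uncertain. Of 20 cell proliferation genes 3 fell, 1 higher and 12 lower adjusted over the list alone (adjusted p = 2.95e-09; adjusted p = 0.0943 with an estimated correlation). These were the mitotic kinase Cdk1 at -1.13 (from 2.06 ± 0.20 to 0.648 ± 0.244 FPKM without LPS), the topoisomerase Top2a at -0.82 and cyclin Ccnb2 at -0.68. Principal cell markers had a median of 0.44, with 0 of 10 past the threshold and 5 higher adjusted over the list alone (adjusted p = 1.01e-07; adjusted p = 0.092 with an estimated correlation). Medulla-enriched markers had a median of 0.36, with 0 of 8 past the threshold and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.0269; adjusted p = 0.13 with an estimated correlation). The mean of these 8 markers was 4.651 to 4.809 log2 units in EtOH and 4.289 to 4.399 in PF, and 4.063 to 4.281 in EtOH_LPS and 3.807 to 4.27 in PF_LPS. Distal convoluted tubule markers had a median of 0.36, with 0 of 8 past the threshold and 4 higher adjusted over the list alone (adjusted p = 0.000163; adjusted p = 0.0769 with an estimated correlation). Proximal tubule transporters had a median of 0.225, with 0 of 38 past the threshold and 7 higher adjusted over the list alone (adjusted p = 4.85e-07; adjusted p = 0.092 with an estimated correlation), and the median was 0.402 with equal total FPKM. Liver markers had a median of 0.51, with 0 of 7 past the threshold and 1 higher adjusted over the list alone (adjusted p = 0.00469; adjusted p = 0.181 with an estimated correlation). Of 3 adipose tissue markers that could be tested Lpl fell, and 2 were lower adjusted over the list alone, with a median of -0.67 and 0 of 3 above 0. The mean of these 3 markers was 5.104 to 5.541 log2 units in the 6 ethanol libraries and 5.755 to 6.4 in the 6 pair-fed libraries. That mean includes Lpl, so it is not separate from the fall of Lpl. Camera found 20 lists up and 6 down, and 0 with an estimated correlation.

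The fold change of the pooled comparison had a Spearman correlation of 0.251 with GC content, and with the GC trend removed 47 genes were higher and 57 lower (45.2% higher instead of 31.1%), 44 of the 45 first called among them. Without PF_LPS library 1 the counts of higher and lower genes were 22 and 54, without library 2 they were 9 and 22 and without library 3 they were 5 and 7. Without EtOH_LPS library 1 they were 10 and 20, without library 2 they were 4 and 7 and without library 3 they were 10 and 14. Leaving out PF library 1, 2 or 3 gave 4 and 8, 4 and 6 or 7 and 6, and leaving out EtOH library 1, 2 or 3 gave 3 and 10, 3 and 5 or 3 and 4. Equal total FPKM moved the median of all genes by 0.14 in this comparison. Pzp stayed past the threshold in 14 of 21 alternatives, Gc in 12, Lpl, Hsd11b1, Limch1 and Epb41l3 in 10, Cyp4a12a and Ces1d in 9, Ctxn3 in 7, Osgin1 in 5 and Slc16a6 in 4. Of 20 alternatives, Synpr stayed past it in 8, Cyp4a12b in 6, Cdk1 and Ccnb2 in 5 and Top2a in 4.

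**Figure D3:**
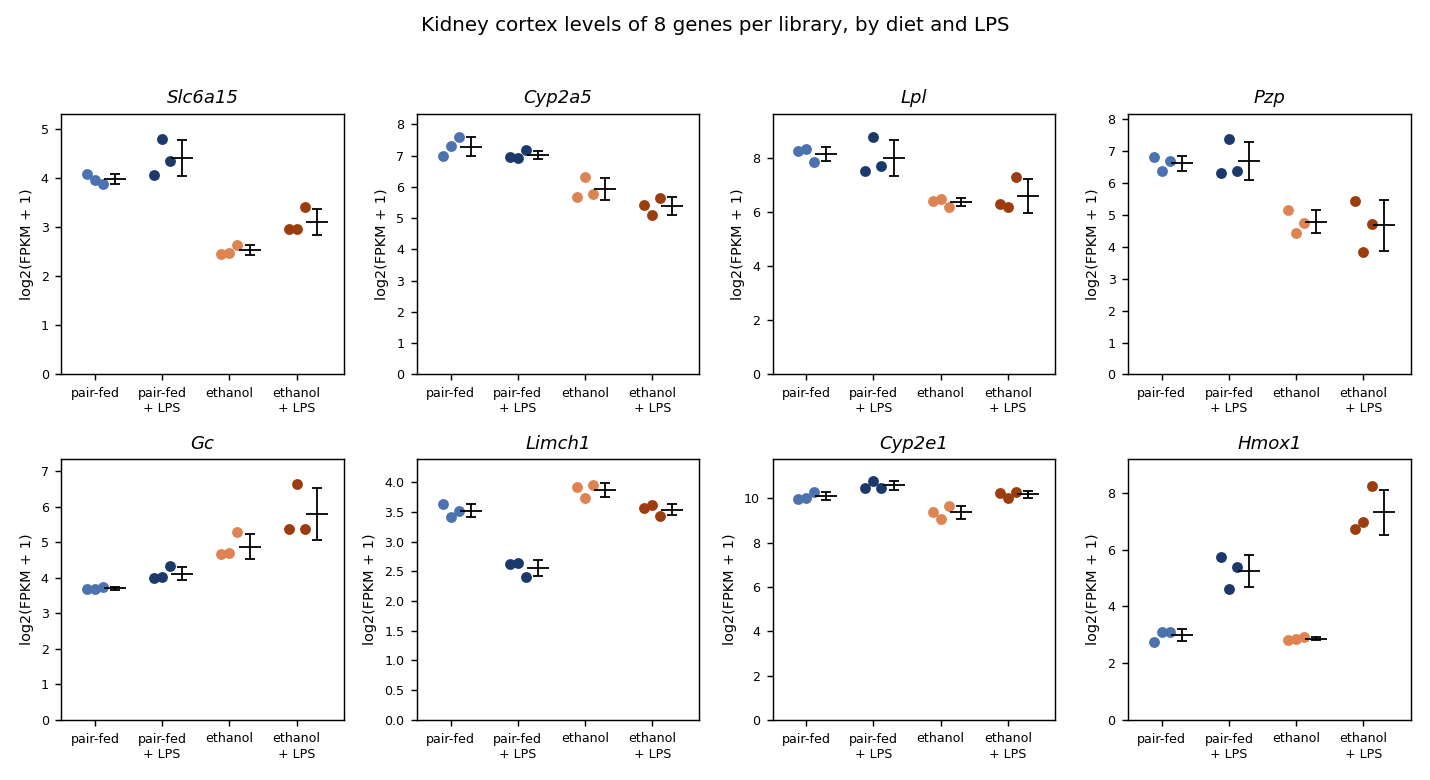
FPKM of 8 genes on a log2(FPKM + 1) axis in the 12 libraries of the 4 groups, with points for libraries and black bars for the mean and SD of 3 libraries. Slc6a15, Cyp2a5, Lpl and Pzp were lower and Gc was higher in ethanol-fed mice, Limch1 with LPS was at 4.90 FPKM in pair-fed and 10.6 in ethanol-fed mice, and Cyp2e1 and Hmox1 did not pass the threshold between diets.

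The interaction asked whether the LPS response differed between diets. By limma 2 genes were higher and 2 lower, Gm23731, Gm22586, Mir1966 and Gm24337, the small RNA genes given above, and 616 genes had an unadjusted p under 0.05. No protein-coding gene was called (0 genes by limma). Cyp24a1, Hmox1 and Angptl4 had interaction values of 3.46 ± 0.90, 2.19 ± 0.51 and 2.33 ± 0.82 log2 units with adjusted p of 0.847, 0.847 and 0.987. The inflammatory genes Il6, Ccl2 and Nos2 had values of 0.68, 0.71 and -1.09 with adjusted p of 0.987, 0.915 and 0.987. The median SE was 0.33, against 0.233 for a comparison of 2 groups. Camera found 10 lists up and 4 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.18. The 30 fatty acid oxidation genes had a median interaction of 0.41, with 0 past the threshold and 0 adjusted over the list alone (camera adjusted p = 2.18e-05; adjusted p = 0.467 with an estimated correlation), and the 38 proximal tubule transporters of 0.37 (adjusted p = 2.18e-05; adjusted p = 0.372 with an estimated correlation). The type I interferon genes had a median of -0.23 (adjusted p = 2.18e-05; adjusted p = 0.467 with an estimated correlation), which was -0.057 with equal total FPKM, a scaling that moved the median of all genes by 0.118 here. The interaction value had a Spearman correlation of 0.333 with GC content. Leaving out PF library 1 or PF_LPS library 2 gave 4 lower genes, PF_LPS library 1 or EtOH_LPS library 2 gave 1, and leaving out EtOH library 1 gave 4 higher genes.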

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

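The tests on values of 1 or a few fragments and on the library of lowest depth were chosen only after the result was seen. The predictions on the GC trend were written before their test, but the correction they use was chosen after seeing the data. After its value was seen, the test on values of a few fragments was limited so that it can exclude that cause but not decide for it. The rule for excluding a cause of a list's median was also made stricter after the values were seen and then returned to its first bound, 0.5 times the first median, with the condition that the list still passes by camera. Under the stricter form, in which the whole interval must keep that bound, the low-depth library was not excluded. The list tests without that library were chosen after the result was seen. Each result in this part was drawn out because the test of the difference between the LPS responses of both diets passed the threshold.

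In the limma fit 4 small RNA genes had such a difference, with fitted interaction values of 4.58 for Gm23731, -4.18 for Gm24337, 3.07 for Gm22586 and -3.96 for Mir1966, which are no bounds, since each gene is listed at 0 in 9 of 12 libraries. In no table was a value found that argues against a technical origin. Per worth of 1 fragment, the values above 0 were equal within a ratio of 1.1 for 2 of the 4 genes, and for 4 of 4 they were whole multiples of the lowest, up to 3, within 5%. Values of 1 or a few fragments on 107 to 126 exonic bases may therefore lie behind these calls, and they cannot be told apart from a difference between groups, because the table holds no fragment counts. Each gene passed the expression filter only through the 3 libraries of the group in which it was above 0, so the filter itself favours such patterns. The drawn splits of the diet labels gave a median of 3 interaction genes, against 4 in the real split.

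For the count of interaction genes, other splits of the diet labels gave as many genes in 49 of 100 draws, the real one included, with 4 genes in the real split and up to 45 in another, so chance is not excluded. That highest count came from swapping the diets in 1 LPS state, which turns the interaction into the pooled ethanol comparison, and without that split the highest other was 9, with 48 of 99 as large.

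By camera 14 lists differed between diets in their LPS response with the preset correlation, and 0 of 50 did with an estimated one. Lists with positive medians were endothelial adhesion and activation at 0.47 (adjusted p = 0.000884; adjusted p = 0.18 with an estimated correlation), endothelial cell markers at 0.20 (adjusted p = 0.0175; adjusted p = 0.515 with an estimated correlation) and extracellular matrix at 0.21 (adjusted p = 0.0343; adjusted p = 0.595 with an estimated correlation). Immediate early genes had a median of 0.46 (adjusted p = 9.65e-05), NF-kB genes of 0.40 (adjusted p = 0.00701) and NRF2 genes of 0.36 (adjusted p = 4.85e-05), each with adjusted p = 0.467 with an estimated correlation. PPAR-alpha targets had a median of 0.35 (adjusted p = 0.0105; adjusted p = 0.474 with an estimated correlation), proximal tubule transporters of 0.37 (adjusted p = 2.18e-05; adjusted p = 0.372 with an estimated correlation) and vitamin D and mineral genes of 0.23 (adjusted p = 0.00909; adjusted p = 0.339 with an estimated correlation). Negative medians were found for type I interferon genes at -0.23 (adjusted p = 2.18e-05), heat-shock genes at -0.30 (adjusted p = 0.00607), neutrophil markers at -0.29 (adjusted p = 0.00607) and lymphocyte markers at -0.52 (adjusted p = 0.0327), each with adjusted p = 0.467 with an estimated correlation. With equal total FPKM the medians were -0.057 for type I interferon genes, -0.118 for heat-shock genes, -0.187 for neutrophil markers, 0.390 for vitamin D and mineral genes, 0.344 for extracellular matrix and 0.306 for endothelial cell markers. Without PF_LPS library 2, at the preset correlation, endothelial cell markers (adjusted p = 0.14), extracellular matrix (adjusted p = 0.125), NF-kB genes (adjusted p = 0.0949), PPAR-alpha targets (adjusted p = 0.14) and lymphocyte markers (adjusted p = 0.0987) no longer passed. Macrophage and dendritic cell markers (adjusted p = 0.00139) and genes of the unfolded protein and integrated stress response (adjusted p = 0.0201) passed, against 0.0651 and 0.0593 with all libraries, so that 11 lists passed in place of 14.

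The 30 fatty acid oxidation genes, picked from these 14 lists after all were seen, had a median interaction of 0.41 with 28 genes above 0, and 0 passed the threshold singly in limma (camera adjusted p = 2.18e-05; adjusted p = 0.467 with an estimated correlation). The tables argue against the GC trend of the libraries as the whole cause, since the median was 0.378 after that trend was removed (bootstrap interval 0.285 to 0.462). They argue in the same way against PF_LPS library 2, the library of lowest depth, as the whole cause. Without it the median was 0.281 (0.159 to 0.347, which reaches below 0.5 times the first median). Camera at the preset correlation then gave an adjusted p of 0.00139 (from 1.65e-05 to 0.467 over the alternatives). Both may still bring part of the value. The intervals resample list members and leave out the spread between libraries, whose list means overlapped after LPS. These means were 6.677 to 7.108 log2 units in PF_LPS and 6.79 to 7.228 in EtOH_LPS, against 6.932 to 7.077 in PF and 6.58 to 6.841 in EtOH. An effect of ethanol on how these genes respond to LPS stays open as a hypothesis, which no separate samples tested here.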

How the results depend on the processing

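The removal of small RNA genes, the GC correction, the omission of the 2 LPS libraries with the strongest GC trend and the list tests without PF_LPS library 2 were chosen after seeing the data, and the other alternatives before. Single named genes were refitted under up to 21 alternatives, which are the pseudocount, both filters, the 3 scalings, the constant prior, the library weights, the replicate block and each library left out, and not under those chosen after seeing the data or with only both groups in the fit. Under these 21, no value of a named gene past the threshold reversed. Over those other than leaving out 1 library, 2796 values of named genes kept direction and side of the threshold, 14 changed sign without being past it in either fit, 3 passed it only in the alternative and 213 only as reported, and with 1 library left out the numbers were 3621, 39, 3 and 441. Of the genes past the threshold that the rule for names took, 109 of 138 were past it in all of these alternatives for LPS in pair-fed mice, 91 of 111 for LPS in ethanol-fed mice, 0 of 4 for ethanol without LPS, 0 of 9 for ethanol with LPS, 2 of 19 for the pooled comparison and 0 of 4 for the interaction. FPKM hold no counts, so the depth behind a low value is unknown, and the estimate of relative depth was lowest in PF_LPS library 2. PF library 1 also had a GC trend relative to its group mean (slope -0.248, against 0.213 in PF library 3) and was kept when the 2 LPS libraries were left out. Where no cause is named, the cause was not tested.

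For LPS in pair-fed mice, 972 genes were lower as reported, 427 with the filter of 5 FPKM (fewer genes tested), 568 with only both groups in the fit (fewer samples) and 2679 with equal total FPKM, which also gave 844 higher in place of 1589. Leaving out 1 library gave 1126 to 1666 higher and 472 to 1085 lower, with 472 without PF library 2 and 502 without PF library 3. For LPS in ethanol-fed mice, 902 genes were lower as reported, 351 with the filter of 5 FPKM, 1861 with equal total FPKM (969 higher in place of 1504), 1558 with library weights and 1395 without the 2 LPS libraries. Leaving out 1 library gave 522 to 1068 lower genes, with 543, 566 and 582 without EtOH library 1, 2 and 3 and 522 and 525 without EtOH_LPS library 2 and 3. The correlation of both LPS responses was 0.701 with a pseudocount of 0.1, 0.699 without a filter and 0.737 with library weights, and the rank correlation 0.506 without a filter, against 0.769 and 0.68.

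For ethanol without LPS (2 higher and 2 lower genes), there were 4 and 4 without a filter, 0 and 0 with the filter of 5 FPKM, 96 and 146 with library weights and 4 and 9 without the 2 LPS libraries. Without small RNA genes limma called 0 and 0. The count at an unadjusted p under 0.05 was 521 over all genes. Lower genes numbered 1 with median-ratio factors, 1 with a constant prior, 13 with only both groups in the fit and 1 to 5 with 1 library left out, with 5 without EtOH library 1 and 1 without PF library 3, EtOH library 2 or 3, or EtOH_LPS library 1 or 2. The library weights did not converge, so their counts are unstable. For ethanol with LPS (5 and 9), there were 2 and 4 with a pseudocount of 0.1, 1 and 0 without a filter, 1 and 1 with equal total FPKM, 2 and 5 with a constant prior, 1 and 0 with library weights, 14 and 16 with the GC correction and 14 and 18 without the 2 LPS libraries. Here 1524 genes had an unadjusted p under 0.05. Lower genes numbered 4 with the filter of 5 FPKM and 5 with only both groups in the fit. Leaving out 1 library gave 1 to 16 higher and 0 to 27 lower. In the order PF, PF_LPS, EtOH and EtOH_LPS library 1 to 3, higher genes numbered 1, 1, 2, 16, 2, 2, 3, 1, 1, 14, 1 and 2, and lower genes 3, 2, 1, 27, 5, 0, 3, 2, 1, 10, 0 and 9.

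For the pooled comparison (14 and 31), there were 4 and 9 without a filter, 5 and 14 with the filter of 5 FPKM, 9 and 17 with equal total FPKM, 38 and 60 with library weights, 1 and 10 without an LPS term and 47 and 57 with the GC correction, with 3 to 22 and 4 to 54 with 1 library left out. In the order PF, PF_LPS, EtOH and EtOH_LPS library 1 to 3, the higher genes were 4, 4, 7, 22, 9, 5, 3, 3, 3, 10, 4 and 10, and the lower genes 8, 6, 6, 54, 22, 7, 10, 5, 4, 20, 7 and 14. For the interaction (2 and 2), there were 4 higher without a filter, 1 higher with a pseudocount of 0.1, 5 and 6 without the 2 LPS libraries, 0 and 0 with the filter of 5 FPKM and 0 and 0 without small RNA genes by limma, where 616 of all genes had an unadjusted p under 0.05. Leaving out 1 library gave 2 to 4 higher and 1 to 4 lower genes, with 4 higher without EtOH library 1, 4 lower without PF library 1 or PF_LPS library 2, and 1 lower without PF_LPS library 1 or EtOH_LPS library 2. With an estimated correlation camera called 7 lists in place of 21, 9 in place of 20, and 0 in place of 14, 26, 26 and 14 in the order of the comparisons above.

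No pairing of the libraries by replicate number was seen, although a weak pairing cannot be excluded with 3 libraries per group. Over 18 pairs of libraries with the same number, the correlation of deviations ran from -0.206 to 0.279 with a mean of 0.014, 5 pairs were over 0.1, and 3 of 12 libraries correlated best with their own number. With the replicate block the counts of higher and lower genes were 1454 and 829 for LPS in pair-fed mice, 1403 and 781 for LPS in ethanol-fed mice, 2 and 1 for ethanol without LPS, 1 and 1 for ethanol with LPS, 3 and 6 for the pooled comparison and 2 and 2 for the interaction.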

Other observations

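The test on the share of proximal tubule was chosen only after the result was seen, while the splits of the samples were chosen before. The prediction on the GC trend was written before its test, but the correction it uses was chosen after seeing the data. The rule for excluding the GC trend was made stricter after its value was seen and then returned to its first bound, and under the stricter form that trend was not excluded.

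Among 16 genes of coagulation and fibrinolysis 9 rose and 1 fell after LPS in pair-fed mice (camera adjusted p = 0.00194; adjusted p = 0.151 with an estimated correlation), and 7 rose in ethanol-fed mice after LPS, 9 adjusted over the list alone (adjusted p = 7.36e-05; adjusted p = 0.0845 with an estimated correlation). The coagulation initiator F3 rose by 2.26 ± 0.35 and 2.91 ± 0.35 log2 units (SE, n = 3 per group, limma). Among 17 p53 targets 8 rose and 1 fell in pair-fed mice, 9 and 1 adjusted over the list alone, with Cdkn1a, an inhibitor of cyclin-dependent kinases, at 2.37 ± 0.25 (adjusted p = 0.0105; adjusted p = 0.225 with an estimated correlation). In ethanol-fed mice 9 rose and 1 fell (adjusted p = 0.00131; adjusted p = 0.159 with an estimated correlation), with Gadd45a at 2.66 ± 0.18. The clock output gene Nfil3 rose by 3.56 ± 0.33 and 3.74 ± 0.33 in pair-fed and ethanol-fed mice. The glycolytic regulator Pfkfb3 rose by 3.32 ± 0.22 and 3.84 ± 0.22. Complement component C3 rose by 5.87 ± 0.41 and 6.37 ± 0.41, and 5 of 14 complement genes rose in each diet. For complement, the camera adjusted p was 0.0196 in pair-fed mice (adjusted p = 0.627 with an estimated correlation) and 0.0755 in ethanol-fed mice, where the median of 0.145 turned to -0.026 with equal total FPKM. The calcium channel Trpv5 rose by 1.81 ± 0.18 and 2.00 ± 0.18, and the phosphate transporter Slc20a1 by 1.92 ± 0.27 and 2.64 ± 0.27. Among 34 matrix and remodelling genes 13 rose and 1 fell in ethanol-fed mice, 14 and 1 adjusted over the list alone, with the metalloproteinase inhibitor Timp1 at 3.31 ± 0.34 (adjusted p = 0.00426; adjusted p = 0.495 with an estimated correlation). With equal total FPKM the list medians were 0.247 in place of 0.699 for coagulation, 0.063 in place of 0.56 for p53 targets and 0.068 in place of 0.426 for complement in pair-fed mice, and 0.376 in place of 0.675 for coagulation and 0.161 in place of 0.413 for matrix genes in ethanol-fed mice.

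The 17 male-biased kidney genes had a median pooled ethanol effect of -0.571, with 4 of 17 genes above 0. In limma 2 fell, and adjusted over the list alone 2 rose and 11 fell (camera adjusted p = 8.58e-06; adjusted p = 0.13 with an estimated correlation). A lower share of proximal tubule, where many of these genes are expressed, is argued against when both LPS states are averaged. The 38 proximal tubule transporters had a pooled median of 0.225 (bootstrap interval 0.111 to 0.366). The median was higher for principal cell (0.443), distal convoluted tubule (0.364), medulla-enriched (0.357) and intercalated cell markers (0.341). It was slightly lower for thick ascending limb (0.211) and podocyte markers (0.208). Without LPS the transporters had a median of 0.074, below all of these other lists (0.173 for podocyte to 0.394 for principal cell markers). With LPS it was 0.383. The male-biased genes had medians of -0.573 without LPS and -0.620 with LPS. The pooled value therefore does not settle the saline state. A smaller share relative to some segments stays open, and a shift between parts of the proximal tubule was not tested. The GC trend of the libraries as the whole cause is argued against by the median of -0.537 after its removal (-0.713 to -0.226, which reaches values smaller than 0.5 times the first median), with a camera adjusted p of 2.38e-05 (from 6.44e-06 to 0.13 over the alternatives). A candidate explanation is a lower androgen signal with ethanol, which stays a hypothesis, since no hormone was measured in these files.

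The libraries were also split in other ways. For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. LPS in pair-fed mice called 2561 genes and at most 4 in another split, with 1 of 10 splits as large, and LPS in ethanol-fed mice 2406 and at most 2, with 1 of 10. Ethanol without LPS called 4 genes and at most 5 in another split, with 3 of 10 splits as large, and ethanol with LPS 14 and at most 6, with 1 of 10. For the pooled ethanol comparison 1 of 100 drawn splits, the real one, gave 45 genes and the highest other gave 9, which argues against chance for that count. The draws covered 100 of 200 possible splits. The count itself ran from 7 without EtOH library 3 to 76 without PF_LPS library 1. The ethanol effects with and without LPS, which share no library, had a Pearson r of 0.084 and a Spearman correlation of 0.143 across 14109 genes. No gene of the adrenal and skeletal muscle lists passed the threshold in any comparison.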
